A study of Mus musculus with 6 samples.

How the data were processed

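Total RNA from cells selected with CD8a magnetic beads out of B16 tumours of female C57BL/6J mice was sequenced as poly-A, strand-specific libraries with molecular identifiers and paired reads. There are 6 libraries, 3 of day 7 and 3 of day 14. Per the labels, the authors' processing notes name Trimmomatic 0.36, featureCounts of Subread 1.5.1 and the genome GRCm38, while the aligner, the use of the molecular identifiers and the strand setting are not given in the sources used here. Values were deposited as RPKM, which the authors made by dividing the reads of each gene by its length in kilobases and by all reads assigned to genes, as recovered from the values. The gene length in bases is given per the file headers. Nothing in the labels says that replicates come from separate animals.

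Each file holds 26754 genes. Value times length times a common factor gave whole reads in every gene, with a largest deviation of 4.08e-05 against a tolerance of 0.001, so the reads of each library could be recovered. Most low read numbers were even (84.0% to 87.7% on day 7, 75.6% to 77.6% on day 14), so both mates of a pair were counted and 2 reads stand for 1 fragment. Libraries held 6523019 to 9313078 reads on day 7 and 11385106 to 13316522 on day 14. CPM are reads scaled to a library of 1000000. A gene without reads gives no limit on a fold change here, because the number of molecules behind the reads is not known. Reads in overlapping gene models appear in both models, so values of overlapping genes are uncertain. Of the gene names, 25661 lie on the same chromosome in GENCODE M21 and 22578 have identical ends, 23 names look like dates, and 1601 genes are shorter than 200 bases.

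Replicates were compared with a chi-square ratio per fragment over genes with 40 or more reads in both libraries together, where 1 means sampling noise alone. The median was 1.11 between day 7 replicates 1 and 2, 40.9 and 44.4 between these and replicate 3, and 4.05 to 4.43 between day 14 libraries. The mean ratio was 1.63 between day 7 replicates 1 and 2, above sampling noise, and 30.4 between replicates 1 and 3. Of 8528 genes at 10 CPM or more in day 7 replicate 1, 0 were absent from replicate 2 and 290 from replicate 3. Of 8424 such genes in replicate 2, 3 were absent from replicate 1 and 287 from replicate 3. Day 7 replicates 1 and 2 were therefore averaged and counted as 1 sample, a choice made after seeing the data.

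The test planned for counts (edgeR with TMM factors) and its DESeq2 alternative were not used, because the files hold RPKM, for which limma on log2(RPKM + 1) was fixed beforehand, although the recovered reads would have allowed a count test. limma 3.58.1 was fitted in R 4.3.3 with 1 coefficient for the day, to genes with a mean of 20 CPM or more over the 5 samples. Each day had precision weights from a loess trend of variance on mean (span 0.3, floor 0.005), followed by moderated t-tests with a trend. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter and weights were chosen after seeing the data, on simulated reads. These assume 8.52 reads per molecule on day 14 and 81.7 on day 7, and 2 times the latter in the averaged day 7 sample. The day 7 number takes the difference between replicates 1 and 3 as sampling of molecules, which was not shown. The rates that follow hold only under this assumption. In 5 simulations of 6604 to 6687 genes, 10.0% of 2-fold, 55.3% of 4-fold, 77.8% of 8-fold and 88.8% of 16-fold changes were recovered. Of 595 calls 20 were false (3.36%), against 11.3% of calls without weights. It was 88.6% without weights and with only an RPKM of 1 or more in 2 samples required, over 13115 to 13188 genes. A list raised on purpose was called in 5 of 5 simulations and 0 of 250 unchanged lists were. Simulated genes varied independently, so these counts do not cover lists whose members vary together.

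Gene lists and cell type markers, 36 in total, were fixed before the files were seen. The 26 lists with 3 or more tested genes were tested with limma camera (correlation 0.01), adjusted over the lists, and again with an estimated correlation and with the fry rotation test. At the preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated one from the number of samples. Members were also counted when adjusted over the list alone. Marker shares of all reads were compared with an exact two-sided permutation test over the 10 splits of 5 samples. Changes per T cell transcript use the summed RPKM of 12 T cell genes fixed beforehand as a scaling factor. Each gene counts in this sum by its RPKM, so the most abundant genes weigh most.

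Named genes follow a rule fixed beforehand. It takes the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM and no overlap between the days, without predicted gene models and receptor segments. It adds 12 genes named in advance, and from each list up to 4 called members with the smallest p, or the 2 with the highest CPM if none was called. Some genes that meet the rule are not reported here. Other settings fixed beforehand were median-of-ratios factors, the T cell scaling, other filters, limma-voom, a replicate block, other thresholds and leaving out each library. Further settings were added after seeing the data. They were 6 libraries counted singly, a pseudocount of 0.1, no weights, and an RPKM of 1 or more in 2 samples with no weights. A minimum of 50 CPM, genes of 200 bases or longer and no mitochondrial genes were added too. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.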

Results

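RNA was sequenced from cells taken out of subcutaneous B16 tumours, a mouse melanoma line grown in C57BL/6J mice, and selected with magnetic beads against CD8a, the alpha chain of the CD8 co-receptor that marks cytotoxic T cells. The samples fall into 2 groups, day 7 and day 14 after the melanoma cells were implanted, with 3 libraries each. The files give RPKM, reads scaled to gene length and library size. Day 7 libraries held 6523019 to 9313078 reads in genes and day 14 libraries 11385106 to 13316522. Day 7 replicates 1 and 2 differed by about the sampling noise, with a median chi-square ratio per fragment of 1.11 where 1 is pure sampling, against 40.9 between day 7 replicates 1 and 3 and 4.05 to 4.43 between day 14 libraries. Their mean was therefore counted as 1 sample, which gives n = 2 for day 7 and n = 3 for day 14. The labels do not say that replicates come from separate mice, so p-values of single genes describe only the spread between these samples. A camera p-value of a list at the preset correlation mainly sets its members against the other genes. It does not measure the spread between samples, and only the version with an estimated correlation takes its degrees of freedom from them. Day 7 libraries had a read in 13133 to 13806 genes and day 14 libraries in 18318 to 19053, a gap that remained after all libraries were thinned to 6500000 reads (13089 to 13806 against 17957 to 18454 genes).

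The labels give 1 comparison, day 14 against day 7. The title of the series names the integrin LFA-1, the IL-2/STAT5 pathway and antibody therapy against PD-1, so the question is how these genes and the T cell programme around them differed between early and later tumours. Called genes of the T cell receptor complex, granzymes, natural killer receptors, the IL-2 receptor beta and gamma chains, LFA-1 and the MHC class I pathway were lower on day 14. Several genes of glycolysis, the hypoxia response, melanocyte pigment and macrophages were higher. With an estimated correlation the T cell receptor, cytotoxic and MHC class I lists kept their call (adjusted p = 0.048 each), and the lists of the other genes named here did not. By the fry rotation test all of these lists passed, with an adjusted p from 0.00043 for the cytotoxic list to 0.0087 for the macrophage list. Across all lists tested, fry left 23 as they were and added a call in 3. Of 6691 genes tested with limma, 548 changed at an adjusted p under 0.05, with 235 higher and 313 lower on day 14 and 1409 genes at an unadjusted p under 0.05. Median-of-ratios scaling, which moves the median log2 fold change of all genes from 0.16 to -0.015, gave 109 higher and 446 lower, so that 19.6% of calls were higher against 42.9%. The balance turned in other settings, with 1455 higher and 722 lower by limma-voom on the recovered reads, 601 and 410 without weights, 981 and 709 with 6 libraries counted singly, and 1346 and 235 without the filter. Leaving out day 7 replicate 3 left 369 changed genes, 147 higher and 222 lower. The summed RPKM of 12 T cell genes fixed as a scaling set was 444 and 426 in the day 7 samples and 120, 124 and 128 in the day 14 samples. Divided by these genes, the median log2 fold change of all genes moved to 1.77, and changes per T cell transcript are given beside named genes whose direction turned.

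**Figure D1:**
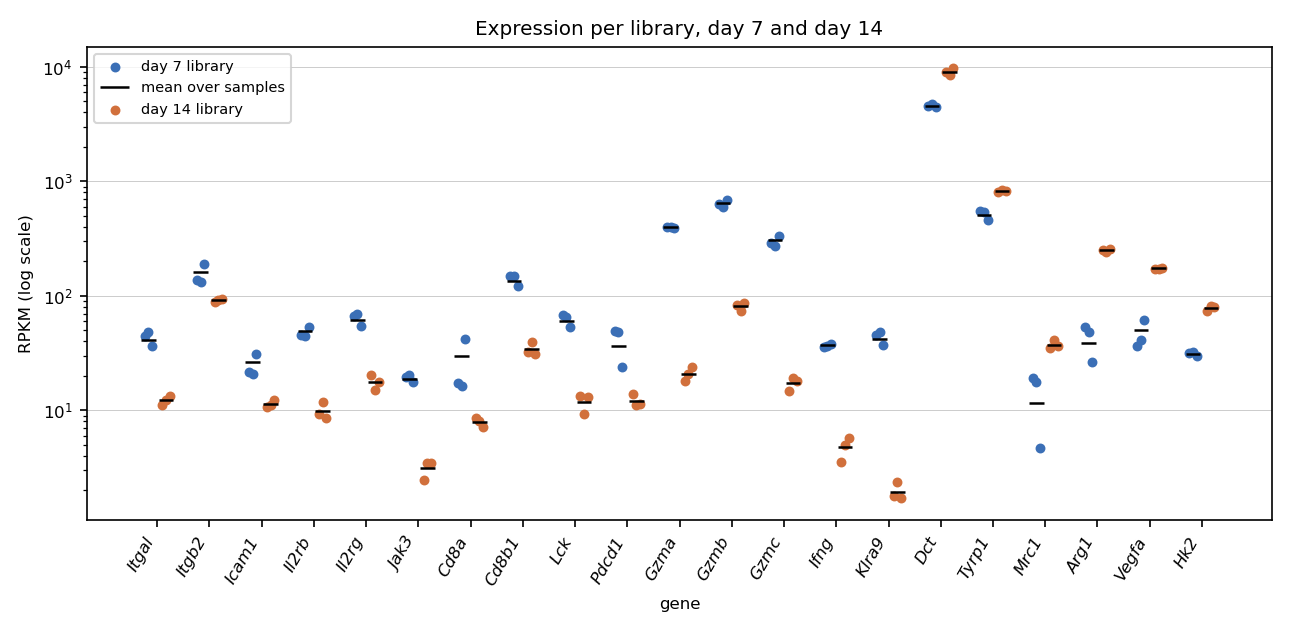
RPKM of 21 genes per library on a log scale, with day 7 in blue, day 14 in orange and a black bar at the mean over samples, where day 7 replicates 1 and 2 count as 1 sample. Itgal averaged 41.3 RPKM on day 7 and 12.3 on day 14, while Dct averaged 4527 and 9110.

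Both subunits of LFA-1 were lower on day 14 as a share of all reads. Itgal, the alpha L chain that pairs with the beta 2 chain to bind ICAM-1 (chromosome 7, 127296260 to 127335138, plus strand of GRCm38), fell from 41.3 ± 6.9 RPKM (SD, n = 2) to 12.3 ± 1.1 (SD, n = 3). Its log2 fold change was -1.66 with an SE of 0.20 (limma adjusted p = 1.56e-07). Itgb2, the beta 2 chain shared with the integrins of macrophages and neutrophils (chromosome 10, 77530252 to 77565708, plus strand), fell from 162 ± 39 to 91.4 ± 3.5 RPKM, a log2 fold change of -0.80 with an SE of 0.15 and an adjusted p of 0.000357. Icam1, the main ligand of LFA-1 (chromosome 9, 21015985 to 21028817, plus strand), fell from 26.2 ± 7.1 to 11.4 ± 0.87 RPKM with an adjusted p of 0.0117. These were the 3 tested members of the list of LFA-1 and its ligands, and all 3 also fell adjusted over the list alone (camera adjusted p = 4.12e-06, and adjusted p = 0.065 with an estimated correlation). Per T cell transcript the direction turned for all 3, to 0.067 for Itgal with a 95% interval of -0.35 to 0.48, to 1.00 for Itgb2 with an interval of 0.67 to 1.32, and to 0.60 for Icam1 with an interval of 0.016 to 1.18. Without day 7 replicate 3 the Itgb2 change was -0.55 with an adjusted p of 0.157, and the call of Icam1 ended too.

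Among 14 tested genes of the signalling that switches LFA-1 to its active state, 5 fell and none rose, with 6 lower adjusted over the list alone. Dock2, a Rac exchange factor of lymphocytes, fell from 28.1 ± 3.7 to 12.2 ± 0.48 RPKM, and Rasgrp1, which links the T cell receptor to Ras, had a log2 fold change of -1.74. The adaptor Skap1 fell from 7.41 ± 5.5 to 1.49 ± 0.52 RPKM and the Rap1 effector Rassf5 from 29.6 ± 21 to 10.6 ± 0.61, while per T cell transcript Dock2 and Rassf5 turned to 0.58 and 0.48. The median log2 fold change of the list was -0.58 and 1.04 per T cell transcript (camera adjusted p = 3.12e-05, and adjusted p = 0.062 with an estimated correlation). Of 11 other integrin subunits tested, Itgb7 fell, from 32.0 ± 15 to 11.9 ± 3.2 RPKM (0.41 per T cell transcript), and the other 10 gave no call, with a list median of 0.12 (camera adjusted p = 0.676). Leaving out day 7 replicate 3 ended the calls of Skap1 and Itgb7, and leaving out day 14 replicate 2 that of Itgb7.

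The receptor side of IL-2 signalling was lower on day 14, with 4 of 7 tested genes down and none up, over all genes and adjusted over the list alone. Il2rb, the beta chain of the IL-2 and IL-15 receptors (chromosome 15, 78480553 to 78495066, minus strand), fell from 49.2 ± 5.7 to 9.88 ± 1.7 RPKM (log2 fold change -2.21, SE 0.29, adjusted p = 5.9e-07). Jak3, the kinase bound to the common gamma chain, fell from 18.8 ± 1.6 to 3.14 ± 0.57 RPKM (log2 fold change -2.27, SE 0.31, adjusted p = 1.9e-06). Il2rg, the common gamma chain (chromosome X, 101264378 to 101268255, minus strand), fell from 61.1 ± 9.6 to 17.7 ± 2.7 RPKM. A second gene model on the same strand, Gm20489, overlaps Il2rg, so its value is uncertain. Jak1 fell with a log2 fold change of -0.69 but turned to 1.05 per T cell transcript with a 95% interval of 0.65 to 1.45, and this was a call that ended without day 7 replicate 3. Il2ra, the alpha chain (chromosome 2, 11642807 to 11693193, plus strand), gave no call at 6.89 ± 0.10 and 3.63 ± 0.25 RPKM (adjusted p = 0.359). Stat5a (chromosome 11, 100859351 to 100885169, plus strand) was at 3.96 ± 0.26 and 2.70 ± 0.13 RPKM (adjusted p = 0.671). Stat5b (chromosome 11, 100780731 to 100850724, minus strand) was at 10.2 ± 4.9 and 9.77 ± 0.72 RPKM (adjusted p = 0.986). The list had a median log2 fold change of -0.77 and 0.72 per T cell transcript (camera adjusted p = 1.62e-06, and adjusted p = 0.062 with an estimated correlation). Per T cell transcript the change was -0.49 for Il2rb with a 95% interval of -1.07 to 0.086, -0.69 for Jak3 with an interval of -1.30 to -0.073, and 0.021 for Il2rg with an interval of -0.53 to 0.57. Of the genes without a call, Il2ra turned to 0.72 (interval -0.13 to 1.57) and Stat5a to 0.93 (0.087 to 1.78), and Stat5b was at 1.62 (0.88 to 2.36).

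Targets of IL-2 and STAT5 did not move as 1 group. Among 11 tested, 2 fell, Gzmb and Tnfrsf9, the co-stimulatory receptor 4-1BB, which went from 24.9 ± 14 to 7.48 ± 2.0 RPKM (0.15 per T cell transcript), and 3 were lower adjusted over the list alone. The median log2 fold change of 0.068 was above 0 while the mean of -0.32 and the camera direction were below it (camera adjusted p = 0.0132, and adjusted p = 0.115 with an estimated correlation). Without day 7 replicate 3 the list's camera adjusted p was 0.0854, and the call of Tnfrsf9 ended.

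T cell receptor and co-receptor genes were lower on day 14 by a similar amount as Itgal. Of 15 tested genes of the T cell receptor complex and pan-T list, 9 fell and none rose, and all 15 were lower adjusted over the list alone, with a median log2 fold change of -1.52 (camera adjusted p = 5.51e-17, and adjusted p = 0.048 with an estimated correlation). Lck, the kinase that starts receptor signalling, fell with a log2 fold change of -2.25 and the adhesion receptor Cd2 with -1.78. Trac, the constant part of the receptor alpha chain, fell from 78.1 ± 15 to 14.9 ± 2.6 RPKM. Cd8b1 (chromosome 6, 71322788 to 71337494, plus strand) fell from 135 ± 18 to 34.3 ± 4.4 RPKM (adjusted p = 1.44e-07). Cd8a, the bead target (chromosome 6, 71373427 to 71379173, plus strand), fell from 29.6 ± 18 to 7.86 ± 0.72 RPKM (adjusted p = 0.000433), a call that ended without day 7 replicate 3, and it stood at 0.029 per T cell transcript. The list took 0.149% ± 0.00038 of reads (SD, n = 2) on day 7 and 0.0484% ± 0.0021 (SD, n = 3) on day 14. All 12 scaling genes belong to this list, so its change per T cell transcript, with a median of 0.029, lies near 0 by construction.

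Genes of cytotoxic granules and effector cytokines had the lowest median change of the gene lists. Of 11 tested, 8 fell and none rose, namely Gzma, Gzmb, Gzmc, Gzmd, Gzmf, Prf1, Ifng and Ctsw. Adjusted over the list alone 8 were lower and 1 higher. Gzmb, the serine protease of killer cell granules (chromosome 14, 56258856 to 56262260, minus strand), fell from 649 ± 49 to 80.7 ± 6.4 RPKM, 8.05-fold (log2 fold change -2.99, SE 0.097, adjusted p = 4.54e-23). Gzma fell from 397 ± 5.3 to 20.9 ± 2.9 RPKM and Gzmc from 306 ± 34 to 17.3 ± 2.2. The cytokine gene Ifng fell from 36.9 ± 1.0 to 4.77 ± 1.1 RPKM. Gzmd averaged 55.2 ± 45 RPKM on day 7 and had 0 reads in the 3 day 14 libraries, and its day 7 value was highest in replicate 3, at 87.3 RPKM against 21.3 in replicate 1. It lies in a family of near-identical granzymes (Gzmd to Gzmg) among which short reads can be split wrongly. The median of the list was -2.48 (camera adjusted p = 7.49e-22, and adjusted p = 0.048 with an estimated correlation). Per T cell transcript all 8 called genes stayed below 0, and 6 had a 95% interval wholly below 0, with -2.41 for Gzma (interval -2.86 to -1.96), -1.19 for Gzmb (-1.42 to -0.96) and -1.07 for Ifng (-1.98 to -0.17). The share of reads of the whole list per scaling gene changed by a log2 of -0.084 (exact permutation p = 0.8). Lamp1 and Srgn, uncalled genes picked out after their values were seen, held 312 and 166 CPM of that sum on day 14. Natural killer receptor genes moved with this list. Klra9, Klra8 and Klre1, the 3 tested of 7 markers, fell from 41.8 ± 6.6 to 1.95 ± 0.36, from 45.7 ± 19 to 4.57 ± 1.2 and from 19.8 ± 5.2 to 3.69 ± 0.83 RPKM, and also adjusted over the list alone (camera adjusted p = 4.07e-08, and adjusted p = 0.062 with an estimated correlation). The Klra genes are another family of close copies, so the split between Klra8 and Klra9 is uncertain.

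**Figure D2:**
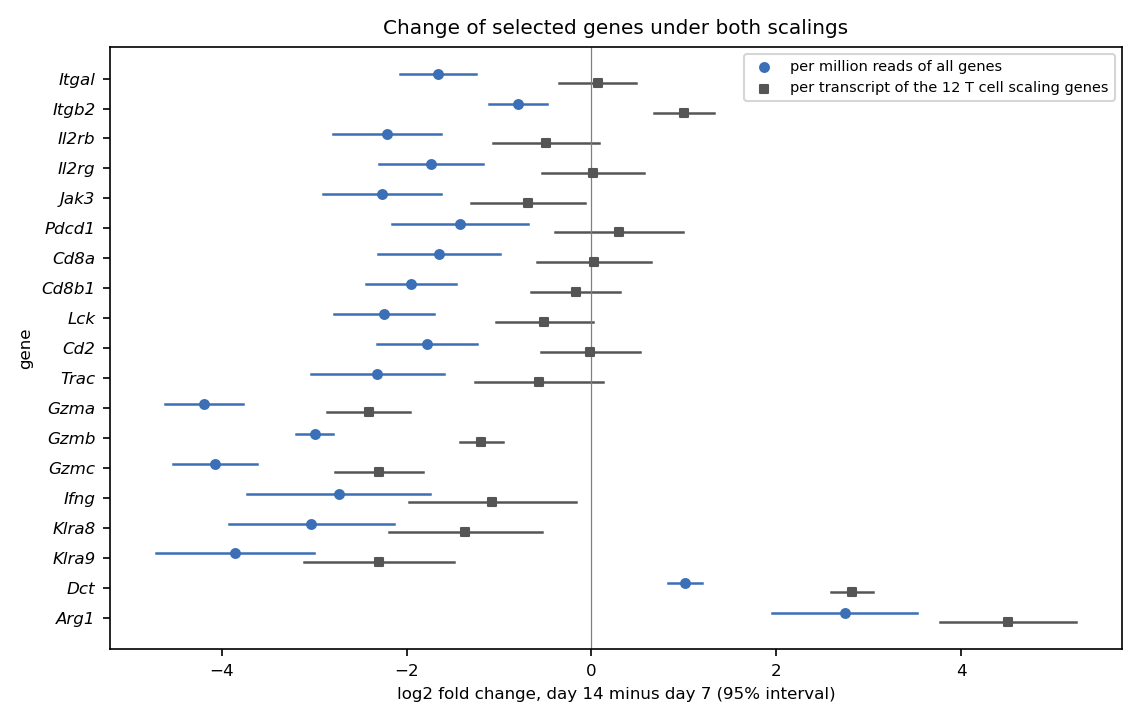
Log2 fold change, day 14 minus day 7, with its 95% interval for 19 genes, scaled to all reads (blue circles) and per transcript of the T cell scaling genes (grey squares). Itgal moves from -1.66 to 0.067 and Itgb2 from -0.80 to 1.00, while Gzma stays below 0 at -4.19 and -2.41.

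Inhibitory receptor and exhaustion genes included 5 that fell and none that rose among 11 tested, with 8 lower adjusted over the list alone. Pdcd1, which encodes PD-1 (chromosome 1, 94038305 to 94052553, minus strand), fell from 36.2 ± 18 to 12.1 ± 1.5 RPKM (log2 fold change -1.42, SE 0.36, adjusted p = 0.00797). Havcr2, which encodes TIM-3, fell from 85.1 ± 1.8 to 33.5 ± 4.3 RPKM (0.45 per T cell transcript), Tigit from 84.0 ± 10.0 to 23.0 ± 0.99 and Cd244 from 15.3 ± 0.21 to 4.13 ± 1.2. The median of -0.95 was 0.72 per T cell transcript, where Pdcd1 stood at 0.30 with a 95% interval of -0.39 to 0.99 (camera adjusted p = 3.85e-06, and adjusted p = 0.062 with an estimated correlation). Cd274, the gene of the PD-1 ligand PD-L1 (chromosome 19, 29367455 to 29388095, plus strand), gave no call at 62.7 ± 5.0 and 76.7 ± 0.89 RPKM (adjusted p = 0.454).

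Of 4 tested naive and memory genes, 2 fell, also adjusted over the list alone, among them Satb1 from 4.35 ± 0.66 to 0.787 ± 0.048 RPKM. The list's camera adjusted p was 0.0483 and was lost in most of the other settings tried (adjusted p = 0.171 with an estimated correlation). The co-stimulatory list had 3 tested genes, of which Cd27, at 33.9 ± 7.2 and 9.06 ± 0.68 RPKM, and Tnfrsf9 fell, and 3 adjusted over the list alone (camera adjusted p = 0.00046, and adjusted p = 0.065 with an estimated correlation). Of 3 tested genes of chemokines and their receptors 1 fell, here and adjusted over the list alone, with a list median of -0.72 (camera adjusted p = 0.0345, and adjusted p = 0.155 with an estimated correlation). None of 6 tissue residency genes was called over all genes and 1 was higher adjusted over the list alone, with Bhlhe40 at 37.6 ± 9.9 and 61.0 ± 5.1 RPKM and Rgs1 at 29.3 ± 4.4 and 36.8 ± 0.85 (camera adjusted p = 0.857). Per T cell transcript the list medians of these 4 groups were 1.05, 0.15, 1.00 and 1.45, so the medians of the 3 groups with called genes turned direction, while Satb1 (-0.40) and Cd27 (-0.076) stayed below 0. The call of Cd27 and those of the naive and chemokine lists ended without day 7 replicate 3.

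Genes of MHC class I presentation were lower on day 14 almost without exception. Of 10 tested, 8 fell and none rose, and all 10 were lower adjusted over the list alone, with a median log2 fold change of -1.09 (camera adjusted p = 6.47e-17, and adjusted p = 0.048 with an estimated correlation). The heavy chains H2-D1 and H2-K1 fell from 628 ± 67 to 328 ± 15 and from 583 ± 50 to 344 ± 20 RPKM. The peptide transporter genes Tap1 and Tap2 fell from 44.7 ± 1.6 to 16.4 ± 2.7 and from 62.3 ± 22 to 19.5 ± 0.84 RPKM. Class II genes fell in 3 of 6 tested members and in 4 adjusted over the list alone, with H2-Ab1 going from 859 ± 112 to 555 ± 19 RPKM, H2-Eb1 from 491 ± 50 to 247 ± 4.2 and the invariant chain Cd74 from 577 ± 92 to 378 ± 6.0 (median -0.61, camera adjusted p = 6.81e-06, and adjusted p = 0.062 with an estimated correlation). Among 16 type I interferon genes, 3 fell and 1 rose, and 6 and 1 adjusted over the list alone (median -0.53, camera adjusted p = 0.000297, and adjusted p = 0.064 with an estimated correlation). Oasl2 fell from 30.7 ± 18 to 11.4 ± 1.7 RPKM and Irf7 from 46.8 ± 2.9 to 21.7 ± 1.0, while the antiviral gene Rsad2 rose from 9.63 ± 7.0 to 34.8 ± 2.5. The H2 and Oas genes are families of close copies. These 3 lists and the falling genes named from them turned direction per T cell transcript (H2-D1 0.87, H2-K1 1.05, Tap1 0.34, Tap2 0.17, H2-Ab1 1.18, H2-Eb1 0.82, Cd74 1.21, Oasl2 0.47 and Irf7 0.68). The list medians became 0.67, 1.17 and 1.22, all below the 1.77 of all genes. Without day 7 replicate 3 the calls of Irf7 and Rsad2 ended.

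Several genes of glycolysis and the hypoxia response moved the other way. Of 15 tested glycolysis genes 9 rose and none fell, and 12 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 0.52 (camera adjusted p = 1.91e-08, and adjusted p = 0.051 with an estimated correlation). Eno1 rose from 402 ± 26 to 607 ± 14 RPKM, Pkm from 375 ± 9.2 to 540 ± 21, Aldoa from 254 ± 23 to 330 ± 10.0 and Hk2, which traps glucose in the cell, from 30.9 ± 1.4 to 78.1 ± 4.3. Hypoxia response genes rose in 5 of 12 tested members, none fell, and 8 rose adjusted over the list alone (median 1.36, camera adjusted p = 4.12e-06, and adjusted p = 0.065 with an estimated correlation). Vegfa, the endothelial growth factor induced by low oxygen, rose from 49.9 ± 16 to 174 ± 2.2 RPKM, Bnip3 from 70.0 ± 28 to 142 ± 4.3, Mxi1 from 7.50 ± 0.27 to 23.6 ± 1.1 and Car9, an acid-base enzyme of hypoxic tumours, from 7.10 ± 0.071 to 44.8 ± 2.9. Oxidative phosphorylation had 3 of 19 genes up and none down, in both ways of adjusting, including adjusted over the list alone (camera adjusted p = 0.0776), namely Atp5b from 316 ± 7.1 to 401 ± 7.6, Cox5b from 72.6 ± 36 to 149 ± 16 and Cox6c from 26.1 ± 2.1 to 51.7 ± 4.2 RPKM. Median-of-ratios scaling ended the calls of Aldoa, Mxi1 and these 3 genes, and leaving out day 7 replicate 3 those of Car9, Mxi1 and Cox6c.

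Cell cycle genes had 4 that rose and 1 that fell among 27 tested, and 5 and 1 adjusted over the list alone (median 0.49, camera adjusted p = 0.0345, and adjusted p = 0.133 with an estimated correlation). Mki67, the proliferation antigen, rose from 94.3 ± 2.0 to 133 ± 4.9 RPKM, Cenpf from 7.54 ± 3.1 to 25.7 ± 2.3 and Ccnb1 by a log2 fold change of 2.35, while Hmgb2 fell from 343 ± 2.4 to 289 ± 7.3. Of 14 immediate-early and heat-shock genes, which tissue handling can induce, Hsp90aa1 rose from 903 ± 38 to 1390 ± 48 RPKM and Hspa8 fell from 1303 ± 70 to 1111 ± 14, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.115). Both falling genes turned direction per T cell transcript, to 1.56 for Hmgb2 and 1.58 for Hspa8. Without day 7 replicate 3 the calls of Hmgb2, Ccnb1 and Hspa8 and that of the cell cycle list ended.

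Melanoma transcripts were abundant in both groups despite the bead selection. The 11 pigment cell markers took 1.43% ± 0.032 of reads (SD, n = 2) on day 7 and 2.61% ± 0.12 (SD, n = 3) on day 14, and 3 rose and none fell, with 6 higher adjusted over the list alone (camera adjusted p = 9.37e-05, and adjusted p = 0.062 with an estimated correlation). Dct, an enzyme of melanin synthesis (chromosome 14, 118012792 to 118052246, minus strand), rose from 4527 ± 136 to 9110 ± 553 RPKM (log2 fold change 1.01, SE 0.090, adjusted p = 1.78e-10). Tyrp1 rose from 504 ± 58 to 827 ± 16 RPKM and Mlana from 112 ± 62 to 268 ± 5.5. Macrophage and monocyte markers rose in 4 of 12 tested members, none fell, and 7 rose adjusted over the list alone (camera adjusted p = 0.000189, and adjusted p = 0.115 with an estimated correlation). Arg1, which breaks down arginine, rose from 38.7 ± 18 to 251 ± 8.8 RPKM, the mannose receptor Mrc1 from 11.5 ± 9.7 to 37.4 ± 3.0, Lyz2 from 207 ± 31 to 383 ± 8.4 and Apoe, which other cells also make, from 501 ± 6.4 to 710 ± 26. The markers took 0.181% ± 0.020 of reads on day 7 and 0.313% ± 0.0036 on day 14. An exact two-sided permutation test of each share of reads gave p = 0.1 for 27 of 34 lists, the smallest p that 10 splits of 5 samples allow (adjusted p = 0.126), so no share could pass the threshold. Leaving out day 7 replicate 3 ended the calls of Mlana, Mrc1 and Lyz2.

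Marker lists of other cell types are set here beside the pan-T list, which took 0.149% of reads on day 7 and 0.0484% on day 14. The red cell list was about as large on day 7 and larger on day 14. Such sums depend on the genes chosen and are not shares of cells. Dendritic cell markers held 0.0588% ± 0.0050 on day 7 and 0.0443% ± 0.0031 on day 14, and 1 of 3 tested, Naaa, fell from 52.3 ± 0.38 to 20.8 ± 0.40 RPKM (0.46 per T cell transcript), also adjusted over the list alone (camera adjusted p = 0.0203, and adjusted p = 0.255 with an estimated correlation). Neutrophil markers held 0.00259% ± 0.00029 and 0.00677% ± 0.00065, with Csf3r, the 1 tested, at 4.11 ± 1.2 and 6.83 ± 0.56 RPKM without a call and S100a9 at 6.79 ± 2.9 and 41.7 ± 6.7. None of 4 tested markers of CD4 and regulatory T cells was called, over all genes or adjusted over the list alone, with Cd4 at 8.68 ± 0.20 and 4.29 ± 1.2 RPKM and Ikzf2 at 4.04 ± 2.4 and 1.46 ± 0.033 (camera adjusted p = 0.175). Both turned from below 0 to 0.64 and 0.29 per T cell transcript. Natural killer markers held 0.0297% ± 0.0075 and 0.00371% ± 0.00055, and markers of gamma-delta T cells 0.00262% ± 0.00093 and 0.00036% ± 5.8e-05, with Trdv4 at 45.2 ± 24 and 3.08 ± 1.7 RPKM. Shares of plasmacytoid dendritic cell and B cell markers were 0.00242% ± 0.0016 and 0.00126% ± 0.00016, and 0.00776% ± 0.0035 and 0.00477% ± 0.00039, with Siglech at 2.47 ± 3.5 and 0.53 ± 0.13 and Ighm at 20.8 ± 8.0 and 20.3 ± 0.49 RPKM. Red cell transcripts did not separate the days, with the 5 markers at 0.146% ± 0.024 and 0.149% ± 0.0094. None of the 5 was called, over all genes or adjusted over the list alone, with Hbb-bs, which has close copies, at 1113 ± 147 and 1145 ± 54 RPKM (camera adjusted p = 0.857). Fibroblast and endothelial markers held 0.00243% ± 0.00047 and 0.00217% ± 0.00047, and 0.00485% ± 0.0013 and 0.00442% ± 0.00019. Keratinocyte and skeletal muscle markers held under 0.001% in either group, and the fat cell and mast cell lists had no read on day 7 and a mean of 5.0e-06% on day 14.

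**Figure D3:**
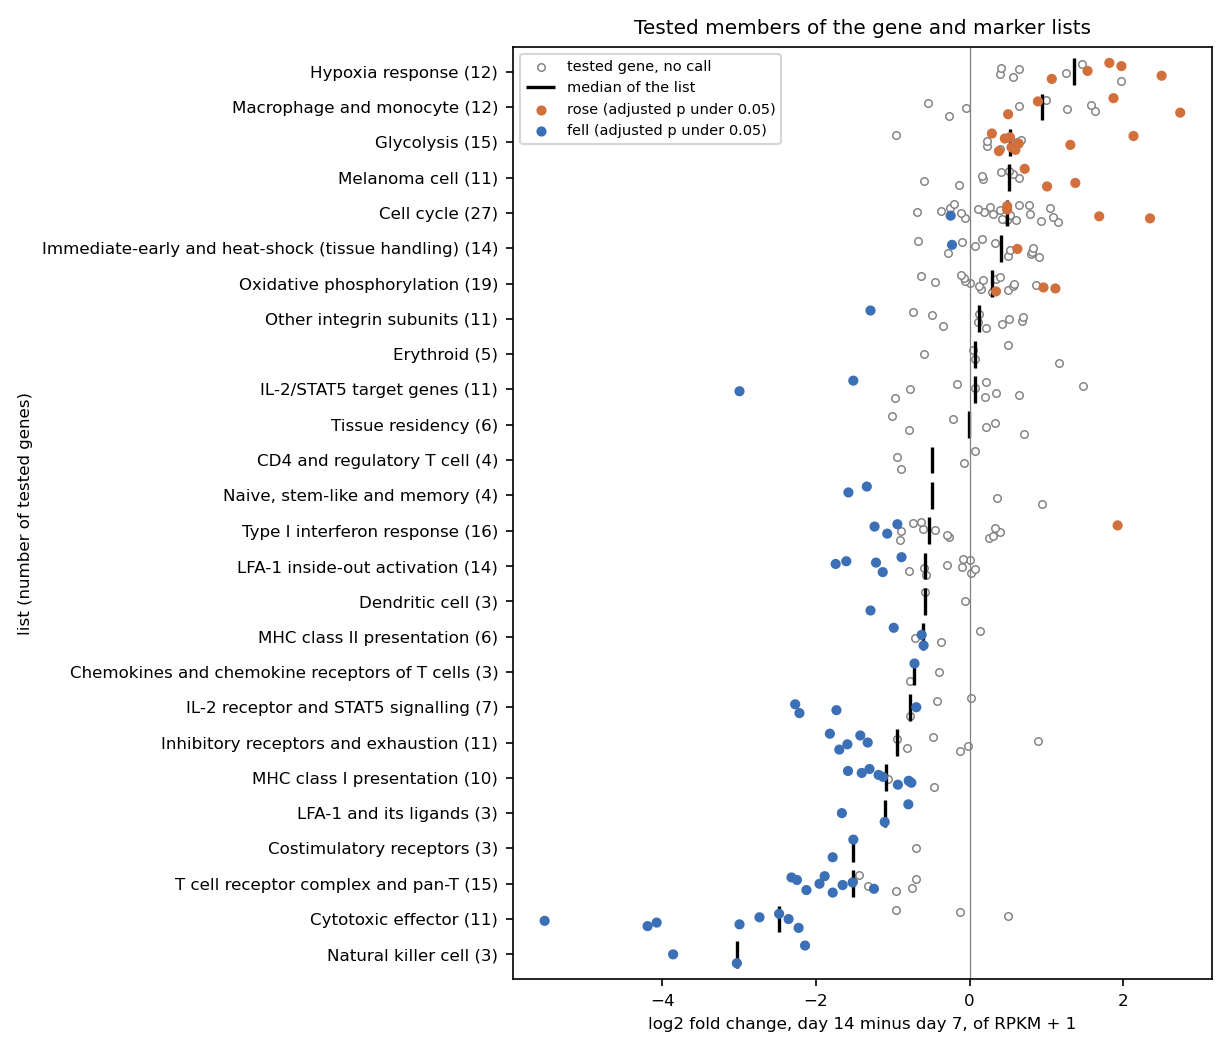
Log2 fold change, day 14 minus day 7, of RPKM + 1 for each tested member of the 26 lists with 3 or more tested genes, coloured where the adjusted p was under 0.05 (orange rose, blue fell), with the list median as a black bar. Medians run from -3.03 for natural killer markers to 1.36 for the hypoxia response, and per T cell transcript 24 of the 26 lie above 0.

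Of the 10 largest rises, Arg1 belongs to the macrophage list and Car9 to the hypoxia list. Marco, a scavenger receptor of macrophages, had no read in the day 7 libraries and 36.2, 32.8 and 35.0 RPKM in day 14 replicates 1, 2 and 3. Cd5l, a secreted macrophage protein, rose from 0.202 ± 0.29 to 21.7 ± 4.4 RPKM. Inhba, a subunit of activin, rose from 0.141 ± 0.020 to 17.8 ± 0.67 RPKM, and the matrix protein gene Cyr61 from 0.575 ± 0.47 to 24.0 ± 2.7. Tubb6 rose from 1.00 ± 0.063 to 19.9 ± 2.3 RPKM, the clotting factor gene F13a1 from 2.65 ± 2.4 to 26.8 ± 3.7 and the fatty acid desaturase Fads2 from 6.07 ± 6.9 to 35.7 ± 0.17. Day 7 replicate 3 sets the day 7 means of both, at 4.37 RPKM for F13a1 and 10.98 for Fads2 against 1.15 and 1.33 in replicate 1. Arg1 and Car9 complete these rises together with Mir5114, a microRNA gene of 61 bases at 0, 0 and 307 RPKM in the day 7 libraries and 625, 579 and 453 on day 14, which lies inside Scd2 on the same strand and cannot be told from it. The largest falls were Gzmd, Gzma, Gzmc, Klra9, Klra8, Gzmb and Ifng with 3 others. Apoa1 and Alb, transcripts made mainly by the liver, fell from 58.9 ± 4.4 to 0.606 ± 0.31 and from 48.5 ± 6.6 to 2.80 ± 1.6 RPKM, and the interferon-induced Gbp11 fell from 18.5 ± 5.2 to 2.00 ± 0.37. Of these 20 genes, limma-voom on the recovered reads did not call Mir5114, Cd5l, Cyr61, Tubb6 or Gzmd, and a pseudocount of 0.1 ended the calls of Fads2 and Car9.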

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

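Of the alternatives, 6 libraries counted singly, the pseudocount of 0.1, no weights and the minimum of 50 CPM were chosen after seeing the data. So were genes of 200 bases or longer, no mitochondrial genes, and an RPKM of 1 or more in 2 samples with no weights. edgeR, DESeq2 and TMM factors were not run. limma was fixed beforehand for files of RPKM, although the recovered reads would have allowed a count test, and limma-voom was the 1 such test run. Scaling by library size alone is already the scaling reported. Without day 7 replicate 3, 1 day 7 sample remains and is assumed to vary like the trend from all samples.

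Against 548 changed genes (235 higher, 313 lower), T cell gene scaling gave 6301 (6283 higher, 18 lower), because it divides by genes that fell. No filter gave 1581 (1346 higher) over 22716 genes, and a CPM of 1 in 3 libraries 1680 (1330 higher). By limma-voom there were 2177 (1455 higher, 722 lower), and with 6 libraries counted singly 1690 (981 higher, 709 lower). No weights gave 1011 (601 higher). An RPKM of 1 or more in 2 samples with no weights gave 1679 (1211 higher) over 13602 genes. Median-of-ratios factors gave 109 higher. A 2-fold minimum left 322 genes (109 higher) and an adjusted p under 0.01 left 354 (132 higher), as stricter thresholds must. Leaving out 1 library at a time gave 147 to 255 higher genes. For the other settings the cause was not tested.

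The replicate block, fitted on 6 libraries, gave 1339 changed genes (734 higher, 605 lower). Correlations of deviations were -0.019, -0.013 and -0.036 between equal replicate numbers and -0.025 to 0.046 between unequal ones. Day 7 replicates 1 and 2 differed by about the sampling noise, so this check cannot decide whether the numbers pair the samples. The labels do not say what the numbers mean.

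Itgal kept its direction and its call in every setting but T cell gene scaling. Itgb2 did so except there and without day 7 replicate 3 (adjusted p = 0.157), with -0.82 to -0.55 when 1 library was left out. T cell gene scaling reversed the log2 fold change of Itgal (0.067), Itgb2 (1.00), Icam1 (0.60), Il2rg (0.021), Stat5a (0.93), Pdcd1 (0.30), Cd8a (0.029), Dock2 (0.58), Rassf5 (0.48), Itgb7 (0.41), Jak1 (1.05), Tnfrsf9 (0.15), Havcr2 (0.45), Hmgb2 (1.56), Oasl2 (0.47), Irf7 (0.68), H2-Ab1 (1.18), H2-Eb1 (0.82), Cd74 (1.21), H2-D1 (0.87), H2-K1 (1.05), Tap2 (0.17), Tap1 (0.34), Hspa8 (1.58) and Naaa (0.46). Of the other results under this scaling 61 kept their call or their lack of one. These include Il2ra (0.72), Cd4 (0.64) and Ikzf2 (0.29), which changed direction without a call in either setting. Marker shares per T cell scaling gene reversed to log2 changes of 0.67 for LFA-1 and its ligands, 1.27 for inside-out activation, 0.52 for the IL-2 receptor, 0.45 for IL-2/STAT5 targets, 0.77 for exhaustion, 0.63 for naive genes, 0.46 for co-stimulation, 0.98 for chemokines, 1.16 for interferon, 1.01 for MHC class II, 0.78 for MHC class I, 0.066 for pan-T genes, 1.29 for dendritic cells and 1.05 for CD4 and regulatory T cells. The cytotoxic share stayed below 0, at -0.084.

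List medians are given here minus the median of all genes. MHC class II stood at -0.60 under T cell gene scaling, where the direction of its test reversed without a call (adjusted p = 0.462). Inside-out activation (-0.74) passed no threshold under T cell gene scaling (-0.73) or with an estimated correlation (-0.74), nor did the IL-2 receptor list with an estimated correlation (-0.93). IL-2/STAT5 targets (-0.087) lost their call with limma-voom (-0.13), 6 libraries counted singly (-0.091), the replicate block (-0.091), no weights (-0.087) and an estimated correlation (-0.087, adjusted p = 0.115), with -0.19 to -0.0089 when 1 library was left out. The fry rotation test left 23 lists as they were and added a call in 3. The estimated correlation ended 17 list calls in all. The estimate was -0.040 for glycolysis, -0.059 for the IL-2 receptor list and -0.044 for inside-out activation, below the preset 0.01. In these lists that argues against correlated members as the cause of the loss. In other lists the estimate lay above the preset, such as 0.31 for LFA-1 and its ligands. The 2 versions also differ in their degrees of freedom. These come from the number of genes with the preset and from the 5 samples with the estimate. The cytotoxic list, with an estimate of -0.038, went from an unadjusted camera p of 2.88e-23 to 0.00187. The few samples thus weaken the test of every list under the estimate. Where the estimate lay above the preset, the 2 parts were not separated.

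On data simulated with 81.7 reads or more per molecule on day 7, 10.0% of 2-fold changes were recovered, so a gene without a call is not shown to be unchanged.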

Other observations

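All tests in this part were chosen after the result was seen, except the test of dominant transcripts and that of genes at 10 CPM or more not expressed on day 7.

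The mitochondrial share of reads was 8.65%, 8.82% and 8.6% in day 7 replicates 1, 2 and 3 and 5.05% to 5.85% on day 14. The transcript Gm10925 took 4.81% to 5.57% and 2.33% to 2.43%. A difference in RNA quality between the days stays open as untested.

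Day 7 libraries read fewer genes than day 14 libraries. After thinning to equal reads the lowest day 14 library still read 4151 more genes than the highest day 7 library, and 4080 more with the mitochondrial and 20 most abundant other genes left out, which argues against depth and dominant transcripts. Of 135 genes at 10 CPM or more in every day 14 library and absent from a day 7 sample, 83.0% (95% interval 75.7% to 88.4%) were at 1 CPM or more in the other day 7 sample, which argues against their not being expressed on day 7. For 4198 genes under 10 CPM the share with a read in the other sample was 55.2%, too near the middle to decide. Few independent molecules behind the day 7 reads stay open, since the slope of the variance over the mean on expression between day 7 replicates 1 and 3 (0.087) was set against a limit of 0.5 that no pair of libraries reached, not even those of different days (0.43 to 0.48).

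Itgal fell with the T cell genes. Per T cell transcript its log2 change was 0.067 with a 95% interval of -0.35 to 0.48, so a lower share of T cell RNA on day 14 could account for it. Markers of other cells did not rise alike. Log2 changes of share were 0.87 for melanoma, 0.79 for macrophages and 0.040 for red cells. They were -0.41 for dendritic cells and -2.99 for natural killer cells. A lower T cell share alone therefore leaves these differences open. Itgb2, which macrophages and neutrophils share, was at 1.00 per T cell transcript against 1.77 for all genes. Its value does not speak against a lower T cell share. A change with the day of the tumour itself stays open as untested.

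Of the 8 called cytotoxic genes, 6 had a 95% interval per T cell transcript wholly below 0, which argues against a lower share of T cell RNA as the whole cause for these 6. The argument is weaker for Prf1 (interval -1.24 to -0.21) and Ifng (-1.98 to -0.17). Their intervals reach above the -0.51 of Lck, which is itself a scaling gene. A lower share of natural killer cell RNA could contribute, since the median log2 change of the natural killer markers was -3.03, below the -2.32 of the pan-T gene that fell most. Natural killer cells are not the target of the CD8a beads. Melanoma cells are not either, yet their markers took 1.43% of reads on day 7 and 2.61% on day 14. How many natural killer cells remained was not measured. Bulk libraries do not say which cells held these transcripts, and a lower level per T cell on day 14 stays open as untested.

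The 5 samples allow 10 splits into 2 and 3, of which 1, the real split, gave 548 changed genes, and the highest of the others gave 0 with limma. These splits are too few for a share under 0.05.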
